A study of Mus musculus with 9 samples.

How the data were processed

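Total RNA of the olfactory mucosa was measured in 9 samples on 1-colour arrays. Per the labels' protocols, RNA was extracted with Trizol and had an RNA integrity number of at least 7, and 1 µg was amplified and labelled with a Cy5 dye. The labels give 27 mice in 3 groups of 9, and per the series' design text the 3 samples of a group were chosen for their olfactory marker protein expression. Control mice received saline for 2 weeks, while the D1 mice were treated for 1 day, so D1 and its control also differ in how long injections lasted. The time of day at collection, the interval since the last dose, the scanner and the software that made the values are not given in the sources used here.

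The authors deposited 1 table of intensity values, 26423 probes by 9 arrays, on a linear scale. The values behave as background-subtracted signals, since 8 to 18 probes per array lie below 0. On each array at least 99.96% of the values are whole multiples of 1 constant, within 0.05 of a step, as after multiplication by 1 factor per array; the target of that scaling stays unknown. Array medians were 1202 to 1447, within the spread of 0.5 on the log2 scale that was set in advance for using the values as deposited, so no further normalization was applied. The table gives no detection calls, no batches and no dates.

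Probes were named through the platform annotation and updated by gene ID through RefSeq's gene table for mouse assembly GRCm38.p6, in which 21825 probes had their gene ID. There were 21876 probes with 1 gene symbol, 0 with several and 4547 with none, which stayed in the tests under their probe IDs. Where a gene had more than 1 probe, as 2424 of 19084 genes did, the probe with the highest mean stood for it, which left 23631 features. No coordinates are given.

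Values were tested as log2(intensity + 50). The pseudocount was chosen after the range of values was seen and before any test, and pseudocounts of 500 and 16 are alternatives. A fold change is on this scale and understates the change of dim genes. One linear model over all 9 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes), with the control, D1 and WK2 groups compared in the 3 possible ways and p-values adjusted by the Benjamini-Hochberg method within each comparison. With 3 arrays against 3, an exact permutation test of 1 gene cannot give a p under 0.1.

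The 39 gene lists, of cell types, processes, responses and gene families, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, with adjustment over 117 tests, and again with an estimated correlation and with fry. Camera at the preset correlation called 27 of the 117, camera with an estimated correlation called 0 (smallest adjusted p 0.744) and fry called 0. Fry's test for change in either direction, which does not compare a list with other genes, called 47. List counts are given over all genes tested and adjusted over the list alone.

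Genes were named by a rule fixed before the data were examined. It takes for each comparison the 8 largest increases and the 8 largest decreases among genes past an adjusted p of 0.05 whose groups do not overlap, leaving out chemoreceptors, predicted genes and immune receptor segments. Where fewer passed, genes of the smallest p fill the places and are given as not passing. It adds up to 4 members of the smallest p from each list described, and always Fkbp5, Tsc22d3, Per1, Sgk1, Nr3c1, Omp, Gap43, Mki67, Krt5 and Cyp2g1. List members and other genes named outside the rule were chosen after their values were seen.

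The gene test was tried on simulated data drawn from the real means and spreads, and on the real arrays with added changes. The list test was tried on the simulated data only. In the simulated D1 arrays the gene test recovered 93% of 100 genes given a 4-fold change and 51% of 100 given a 2-fold change. It also called 8 unchanged genes there, and 9 in each simulated comparison with WK2. On the real arrays it recovered 98% and 66% for WK2 against control, and 96% and 57% for WK2 against D1. It also called 831 and 124 other genes there, beside 379 and 22 calls with no change added. The 200 genes were changed in the same run, and the adjusted cutoff loosens as more genes change. A list moved by 0.5 on the log2 scale was called in each of the 3 comparisons, and 0 of 36 unrelated lists were. The simulated genes were drawn independently of each other, so this cannot show false calls from correlation between members of a list. Estimated correlations in the real lists reached 0.67, for MHC class II genes.

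Alternatives were quantile normalization, median centring, cyclic loess, leaving out the dimmest 25% or 50% of features, the mean of a gene's probes, trend and robust moderation, the replicate number as a block, a fit of the 2 groups compared, array weights, a larger pseudocount, an adjusted p under 0.1, a minimum fold of 2 and leaving out each array. A smaller pseudocount, leaving out 2 arrays together and a covariate for the main axis within groups were added after the data were seen. Medians relative to features of the same intensity, in 10 bins of nearly equal size, with intervals from 1000 bootstrap draws of list members, were also added then. Chance values for comparisons that share the control arrays came from 100 simulations of unchanged groups.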

Results

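RNA from the olfactory mucosa, the nasal lining that holds the olfactory sensory neurons, was measured on 9 single-colour arrays from male C57BL/6 mice aged 6 to 8 weeks. The arrays fall into 3 groups of 3. The control group received saline for 2 weeks. The D1 group received dexamethasone at 1 mg/kg for 1 day, and the WK2 group received it daily at the same dose for 2 weeks. Dexamethasone is a synthetic glucocorticoid, an agonist of the glucocorticoid receptor. Each group held 9 mice, and the samples put on arrays were those picked for their expression of Omp, which encodes olfactory marker protein of mature olfactory neurons. The level of Omp was therefore part of the selection and is no independent finding. The choice may also have affected genes that vary with Omp between samples, such as those of mature olfactory neurons and the olfactory receptors. This was not tested and limits every result on them below. Nothing in the labels says that the 3 samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Median probe intensity was 1202 to 1447 per array, and Pearson's r across features, which are not independent replicates, was 0.977 to 0.993 between arrays of 1 group. The number of arrays limits the precision of every value.

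The comparison of D1 with control asks what 1 day of dexamethasone changed. No single gene passed the test, so the genes given first are from those with the smallest p in each direction. Prss35, a serine protease family member, had a log2 difference of -1.10 ± 0.17 (SE), with an intensity of 630 ± 70.9 (SD, n = 3) in control and 269 ± 46.7 in D1. Calcr, the calcitonin receptor, differed by -1.08, Cd109 by -0.85 and Lox, which cross-links collagen, by -0.81. Cthrc1, a secreted collagen triple helix repeat protein, stood at 2887 ± 146 in control and 1427 ± 216 in D1. On the higher side, Clec2d differed by 0.97, Atp6v0a4, a proton pump subunit, by 0.85, Dbp, a clock output transcription factor, by 0.78 and Tbc1d10a by 0.73. Among textbook targets of the glucocorticoid receptor, Tsc22d3 differed by -0.68 ± 0.28 (SE), Zbtb16 by -1.49 ± 0.36, Fkbp5 by -0.53 ± 0.29, Mt1 by 0.34 ± 0.14, Sgk1 by 0.28 ± 0.23 and Per1 by 0.22 ± 0.24, and the receptor gene Nr3c1 by -0.09 ± 0.21. None of these passed the test, and Sgk1 lay at -0.01 without control replicate 2 and Nr3c1 at 0.04 without D1 replicate 3.

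The limma test over 23631 features called 0 genes in D1 against control at an adjusted p under 0.05, and its smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 475 genes, where 1182 would be expected by chance. This count depended on the fit. It was 1702 with array weights (smallest adjusted p 0.124, limma) and 1101 without control replicate 2 and WK2 replicate 3. With the covariate for the axis within groups it was 790, and without D1 replicate 2 it was 297. A count below chance therefore does not show that nothing changed. Trend and robust moderation also called 0. Leaving out control replicate 1 called 1 gene, Muc19, and leaving out control replicate 3 called 1 gene, Qrich2, both chosen for mention after their values were seen. After genes were given a 4-fold change in the D1 arrays as a test, 91% of 100 were recovered, and 35% of 100 given a 2-fold change. All 200 genes were changed in the same run, and the adjusted cutoff loosens as more genes change. Recovery of 1 gene changed alone was not tested and would be lower.

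Of the lists fixed before the data were examined, bone and cartilage genes stood lowest in D1. Of 25 measured members, 23 lay below control, with a median of -0.41, and 0 passed over all genes or adjusted over the list alone. Ibsp, bone sialoprotein, differed by -0.97, Smpd3 by -0.79, Col11a1 by -0.64 and the osteoclast protease gene Ctsk by -0.62. Of 39 extracellular matrix genes 33 lay below control, with a median of -0.20. None passed over all genes, while 3 fell when adjusted over the list alone: Lox (-0.81), Col5a2 (-0.77) and Col1a2 (-0.74). The camera test with a preset correlation called both lists lower, at adjusted p = 1.67e-12 for bone and cartilage and 1.92e-10 for matrix. Neither held, with adjusted p = 0.744 and adjusted p = 0.882 with an estimated correlation.

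Neutrophil genes had a median of 0.57 in D1, with 21 of 24 above control and 0 past the test. Ctsg, cathepsin G, differed by 1.05 ± 0.60 (SE) and Mmp9 by -0.39 ± 0.23. The secretory gland list had a median of 0.18, with 20 of 27 members above control, among them Dmbt1 at 1.62 ± 0.68 and Lyz1, lysozyme, at 0.86 ± 0.32. The preset camera test called the neutrophil list higher at adjusted p = 0.00515 and the gland list at adjusted p = 0.0301, with adjusted p = 0.943 for both with an estimated correlation. Without D1 replicate 2 the neutrophil median was 0.10 and the test turned to the lower side at adjusted p = 0.783. The neutrophil call also ended without control replicate 1 (0.942) and without control replicate 3 (0.146), and the median was 1.198 without control replicate 2 and 0.97 without D1 replicate 3. Erythroid genes moved with the same arrays. Their list had a median of 0.13 in D1 and was not called (preset camera, adjusted p = 0.624). It was called higher without control replicate 2 (median 0.45, adjusted p = 4.70e-06) and without D1 replicate 3 (median 0.39, adjusted p = 0.000944). The gland call ended under quantile normalization (0.419) and without control replicate 1 (0.316), control replicate 3 (0.256) or D1 replicate 2 (0.266).

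Mature olfactory neuron genes had a median of -0.11 in D1, proliferation genes -0.08, MHC class II genes -0.20, glucocorticoid-induced genes -0.02 and olfactory receptor genes -0.03. In these 5 lists 0 genes passed over all genes or adjusted over the list alone. Over 23 alternatives the medians ran from -0.17 to 0.01 (mature neurons), -0.19 to -0.02 (proliferation) and -0.53 to -0.03 (MHC class II). They ran from -0.07 to -0.01 for glucocorticoid-induced genes and from -0.12 to 0.05 for olfactory receptors. MHC class II members with the smallest p were Cd74 at -0.75 and H2-Ob at -0.46, and proliferation members were Top2a at -0.40 and Bub1 at -0.39. The preset camera test called each of the 5 lists lower, at adjusted p = 0.0111 for the mature neuron and proliferation lists, 0.0223 for MHC class II, 0.0428 for the glucocorticoid-induced list and 0.0148 for olfactory receptors. With an estimated correlation the first 4 had adjusted p = 0.943 and the receptors adjusted p = 1.00. Without control replicate 2 the calls of the mature neuron (adjusted p = 0.569), proliferation (0.905), MHC class II (0.905) and glucocorticoid-induced (0.385) lists ended. The mature neuron call also ended without D1 replicate 2 (0.767, with the median at 0.01), the proliferation call without D1 replicate 3 (0.304) and the receptor call without control replicate 1 (0.930, with the median at 0.05) or D1 replicate 1 (0.0601). The MHC class II call ended without control replicate 1 (0.113), D1 replicate 1 (0.390) or D1 replicate 3 (0.385), and the glucocorticoid-induced call without control replicate 3 (0.0530), D1 replicate 1 (0.318) or D1 replicate 3 (0.0595). Under cyclic loess the mature neuron (0.0894), MHC class II (0.0911) and glucocorticoid-induced (0.210) calls ended, and the last 2 also under quantile normalization (0.112 and 0.166) and median centring (0.0516 for both).

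The comparison of WK2 with control asks what 2 weeks of daily dexamethasone changed. The chemokine genes Cxcl1, Ccl20 and Ccl11 rose. Cxcl1, a neutrophil attractant, was 5.87-fold higher (log2 2.55 ± 0.36 SE, adjusted p = 0.0326, limma), at 240 ± 12.2 in control and 1840 ± 944 (SD, n = 3) in WK2. Ccl20 was 5.35-fold higher (adjusted p = 0.0395) and Ccl11, eotaxin, 3.52-fold higher (adjusted p = 0.0308). Zbtb16, a glucocorticoid receptor target, was 5.41-fold lower (log2 -2.44 ± 0.36, adjusted p = 0.0347), at 2114 ± 701 in control and 344 ± 101 in WK2. Fkbp5, another such target, lay at -1.29 ± 0.29 with an adjusted p of 0.0551 and did not pass, though it did in 7 of 23 alternatives, among them without WK2 replicate 1 (0.0419). The calls of Cxcl1, Ccl20, Ccl11 and Zbtb16 each ended without control replicate 1 (adjusted p = 0.0917 for each), without control replicate 3 (0.148 for each) and without WK2 replicate 3 (0.0794, and 0.0780 for Ccl11). Without control replicate 2 the calls of Zbtb16 (0.0688), Cxcl1 (0.0778) and Ccl20 (0.0855) ended, and without WK2 replicate 2 those of Ccl20 (0.0713), Ccl11 and Zbtb16 (both 0.0852). Without D1 replicate 1 those of Cxcl1 (0.0538), Ccl20 (0.0641) and Ccl11 (0.0531) ended, without D1 replicate 2 those of Ccl11 (0.0561) and Zbtb16 (0.0563), and without D1 replicate 3 those of Zbtb16 (0.0530), Cxcl1 (0.0578) and Ccl20 (0.0718).

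**Figure D1:**
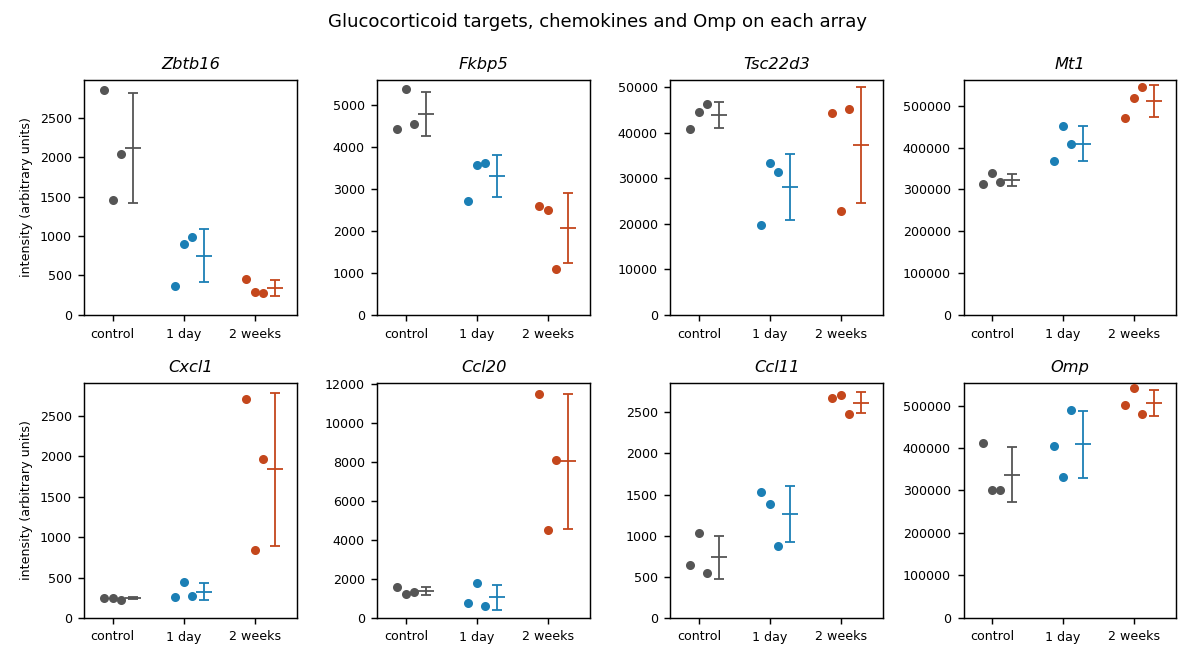
Intensity (arbitrary units, linear axis from 0) of glucocorticoid receptor targets, chemokines and Omp on each of the 9 arrays, with 1 point per array and a bar for the mean with its SD in each group of 3. Mean Zbtb16 intensity was 2114 in control, 751 in D1 and 344 in WK2, and mean Ccl20 intensity was 1371, 1050 and 8039.

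Clock genes moved in opposite directions in WK2. Dbp fell 4.41-fold (log2 -2.14 ± 0.22 SE, adjusted p = 0.0176, limma), from 40950 ± 9218 in control to 9263 ± 2020 (SD, n = 3) in WK2. Tef, a related transcription factor, fell 3.10-fold and the period gene Per2 3.01-fold, both at adjusted p = 0.0176, and Ciart, a repressor of the clock, had a log2 change of -1.16 (adjusted p = 0.0419). Arntl, which encodes the activator BMAL1, rose 2.45-fold (adjusted p = 0.0278). Of 17 measured circadian genes, 1 rose and 4 fell over all genes, and 2 rose and 7 fell adjusted over the list alone. The list's median was -0.24, and the preset camera test called it lower (adjusted p = 0.00906), with adjusted p = 0.943 with an estimated correlation; the call ended under quantile normalization (0.0929) and cyclic loess (0.0699). Without control replicate 3 the calls of Dbp (0.0838), Tef (0.12), Per2 (0.12) and Arntl (0.148) ended, and without WK2 replicate 2 those of Dbp and Tef (both 0.0508), Per2 (0.0588) and Arntl (0.0713). Without WK2 replicate 3 those of Tef (0.0559) and Per2 (0.0617) ended, without control replicate 1 those of Per2 (0.0629) and Arntl (0.0880), and that of Arntl also without control replicate 2 (0.0658) or D1 replicate 1, 2 or 3 (0.0538, 0.0561 and 0.0578).

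**Figure D2:**
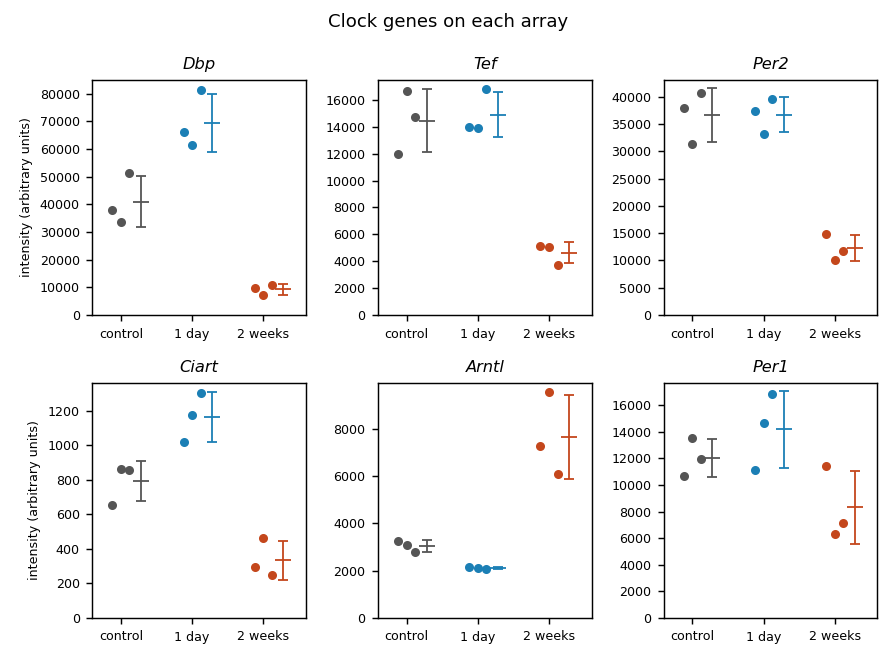
Intensity (arbitrary units, linear axis from 0) of 6 clock genes on each of the 9 arrays, with 1 point per array and a bar for the mean with its SD in each group of 3. Mean Arntl intensity was 3048 in control, 2121 in D1 and 7659 in WK2, while mean Dbp intensity was 40950, 69510 and 9263.

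The other genes with the largest changes in WK2 were of mixed kinds. CK137956 rose 8.31-fold (adjusted p = 0.0410, limma), Asz1, a germ cell gene, 3.92-fold (adjusted p = 0.0498), Btg4 3.76-fold (adjusted p = 0.0176), Ly6g6d 3.12-fold (adjusted p = 0.0419) and Cyp26a1, which degrades retinoic acid, 2.99-fold (adjusted p = 0.0427). Wdfy1 fell 4.70-fold (adjusted p = 0.0210), Safb2 3.21-fold (adjusted p = 0.0410), Nphs1, nephrin, 3.03-fold (adjusted p = 0.0395) and Apcdd1, a Wnt inhibitor, 3.02-fold (adjusted p = 0.0176). The calls of Asz1, Cyp26a1, Safb2 and Nphs1 ended with any 1 array left out except WK2 replicate 1. A dimmer probe of Wdfy1 gave a log2 change of -0.71 beside -2.23 on the brighter one, and a dimmer probe of Nphs1 gave -0.71 beside -1.60.

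In all, 379 features passed the limma test in WK2 against control, 101 higher and 278 lower, of which 331 were named genes. In every one of the 379 the values of both groups did not overlap, as in 37.6% of all features, where chance gives 10%. The fit of the control and WK2 arrays alone called 0 genes, with 5787 at an unadjusted p under 0.05. Leaving out 1 array left 9, 37 or 2 genes (control replicates 1, 2 and 3), 15, 22 or 14 (D1 replicates 1, 2 and 3) and 966, 1 or 5 (WK2 replicates 1, 2 and 3). The 52 calls of named genes in both comparisons with WK2 shrank to 14, 21 or 6, to 9, 11 or 8 and to 40, 9 or 7 in the same order.

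Inflammation genes stood above control in 40 of 49 cases in WK2, with a median of 0.31. The median over all features was 0.14 in this comparison, so the list stood 0.18 above it. Cxcl1, Ccl20 and Ccl11 rose over all genes and 6 members rose and 1 fell adjusted over the list alone; Cxcl2 lay at 1.65 (adjusted p = 0.0548). The camera test did not call the list (adjusted p = 0.0685), though it did in 6 of 23 alternatives, among them without control replicate 2 (0.0162) or D1 replicate 2 (0.0336). In the glucocorticoid-induced list of 38 genes, Mt1, a metallothionein, rose 1.58-fold (log2 0.66 ± 0.14 SE) and Zbtb16 fell, with 2 higher and 5 lower adjusted over the list alone, among them Dusp1 (0.59), Fkbp5 and Mertk (-0.68). The median was -0.10 and camera did not call this list either (adjusted p = 0.111), but called it lower without WK2 replicate 1 (0.0148). Sgk1 had a difference of 0.51, Per1 of -0.58, Tsc22d3 of -0.29 and the receptor gene Nr3c1 of 0.08, and none of these passed. Tsc22d3 lay at 0.03 without WK2 replicate 2, and Nr3c1 at -0.01 under median centring, -0.01 without control replicate 1 and -0.11 without WK2 replicate 3.

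Some bone and matrix genes fell in WK2. Of those given for D1, Lox lay at 0.06 (-0.48 on its dimmer probe), Col1a2 at 0.02, Col5a2 at 0.25, Ibsp at 0.39 and Smpd3 at -0.62 against control, and none of these passed. Dmp1, a bone matrix gene, fell 2.90-fold (adjusted p = 0.0349, limma) and Col9a1, a cartilage collagen, 1.89-fold (adjusted p = 0.0406). Timp3 fell 2.40-fold (adjusted p = 0.0347), Loxl1 2.15-fold (adjusted p = 0.0492), Col18a1 1.98-fold and Fbln2 1.86-fold (both adjusted p = 0.0419). The limma calls of Col9a1, Timp3 and Col18a1 ended with any 1 array left out except WK2 replicate 1 (adjusted p up to 0.148). That of Dmp1 ended with any 1 array left out except control replicate 2 or WK2 replicate 1. Of 25 bone and cartilage genes, 2 fell over all genes and 5 adjusted over the list alone, the other members being Comp (-1.25), Col9a2 (-0.73) and Col9a3 (-0.57), with a median of -0.53. Of 39 matrix genes 17 lay above and 22 below control; 4 fell, and 8 fell and 3 rose adjusted over the list alone, with a median of -0.14. The preset camera test called both lower (adjusted p = 0.000352 and 0.0148), with adjusted p = 0.943 for both with an estimated correlation. The matrix call ended under quantile normalization (0.112), cyclic loess (0.140), without control replicate 3 (0.0544, with the median at -0.06) and without WK2 replicate 2 (0.125, with the median at -0.07). Without the dimmest 50% of features both calls ended (0.123 for bone and cartilage, 0.471 for matrix). Over 23 alternatives the bone and cartilage median ran from -0.63 to -0.18.

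Olfactory neuron markers, which the choice of samples by Omp may have affected, were mixed in WK2. Dpysl5, a growth cone gene of immature neurons, fell 2.40-fold (adjusted p = 0.0395, limma), and Crmp1 lay at -1.34, Ncam1 at -0.75 and Dclk1 at -0.66 without passing. The Dpysl5 call ended with any 1 array left out except WK2 replicate 1 (adjusted p 0.0641 to 0.148, limma). Of 22 immature neuron genes, 1 fell over all genes and 4 adjusted over the list alone, with a median of -0.20. The preset camera test called this list lower at adjusted p = 0.00222, with adjusted p = 0.943 with an estimated correlation. Of 25 mature neuron genes 0 passed over all genes, while 2 rose and 4 fell adjusted over the list alone, and camera did not call the list (adjusted p = 0.161), but called it lower under quantile normalization (0.0220). Omp lay at 0.60 ± 0.19 (SE, adjusted p = 0.0852), Gng13 at 0.52, Gfy at -1.05, and Gap43, an immature neuron marker, at -0.27.

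Vascular genes had a median of -0.26 in WK2. Notch3, a receptor of vessel wall cells, fell 1.73-fold (adjusted p = 0.0498, limma), and Tie1 lay at -0.79, Robo4 at -0.65 and Flt1 at -0.60 without passing. Of 25 vascular genes, 1 fell over all genes and 4 adjusted over the list alone, and the preset camera test called the list lower at adjusted p = 0.00423, with adjusted p = 0.943 with an estimated correlation. Kit, a receptor found on basal cells and mast cells, fell 2.16-fold, Trpc2, a channel of vomeronasal neurons, 2.37-fold, Olig2 1.97-fold, Stat2 1.89-fold and Cyp1a1 1.95-fold. Each of these was the 1 member of its list that passed, except that Kit stood in both the globose basal and mast cell lists. The calls of Kit, Stat2 and Cyp1a1 ended with any 1 array left out except WK2 replicate 1. The basal cell keratin genes Krt5 and Krt14 lay at 0.60 and 0.66, and Cyp2g1, a sustentacular cell enzyme, at 0.55, without passing. Quantile normalization put Cyp2g1 at -0.03. The probe used for Mki67, a proliferation marker, lay at -0.74 and its other probe at 0.21.

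Ribosomal, oxidative phosphorylation and chemoreceptor genes stood above control in WK2. The median over all features was 0.14 in this comparison and 0.02 after quantile normalization, so these lists are given relative to all features. The change also varied with intensity, among 10 bins of features by mean intensity. Medians were 0.27 in bins 2, 3 and 4 from the dimmest, -0.07 in bin 8 and 0.10 in bin 10. Ribosomal protein genes had a median 0.37 above all features, and Rpl38 rose 2.33-fold (adjusted p = 0.0497, limma), with 11 members higher adjusted over the list alone. Oxidative phosphorylation genes stood 0.26 above all features, with 0 past the test over all genes or adjusted over the list alone. Among 548 olfactory receptor genes, 0.14 above all features, 5 rose over all genes and 1 adjusted over the list alone, the 5 being Olfr173 (2.99-fold), Olfr592 (2.09-fold), Olfr1009, Olfr1356 and Olfr1120, named after their values were seen. Tas2r126, a bitter taste receptor gene, rose 2.31-fold and was the 1 gene that passed in the taste and trace amine receptor list, and 0 vomeronasal receptor genes passed. Relative to features of the same intensity bin, a comparison chosen after the values were seen, the medians were 0.08 for olfactory, 0.10 for vomeronasal and 0.14 for taste and trace amine receptors, 0.46 for ribosomal and 0.29 for oxidative phosphorylation genes.

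The preset camera test called the ribosomal (adjusted p = 0.000397), oxidative phosphorylation (0.00325), olfactory receptor (0.00123), taste and trace amine receptor (0.00181) and vomeronasal receptor (0.0289) lists higher in WK2. With an estimated correlation the olfactory receptors had adjusted p = 0.945 and the other 4 lists adjusted p = 0.943. The oxidative phosphorylation call ended without WK2 replicate 3 (0.0789). The vomeronasal receptor call ended under quantile normalization (0.119), cyclic loess (0.142), without control replicate 2 (0.0731) and without WK2 replicate 1 (0.187).

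**Figure D3:**
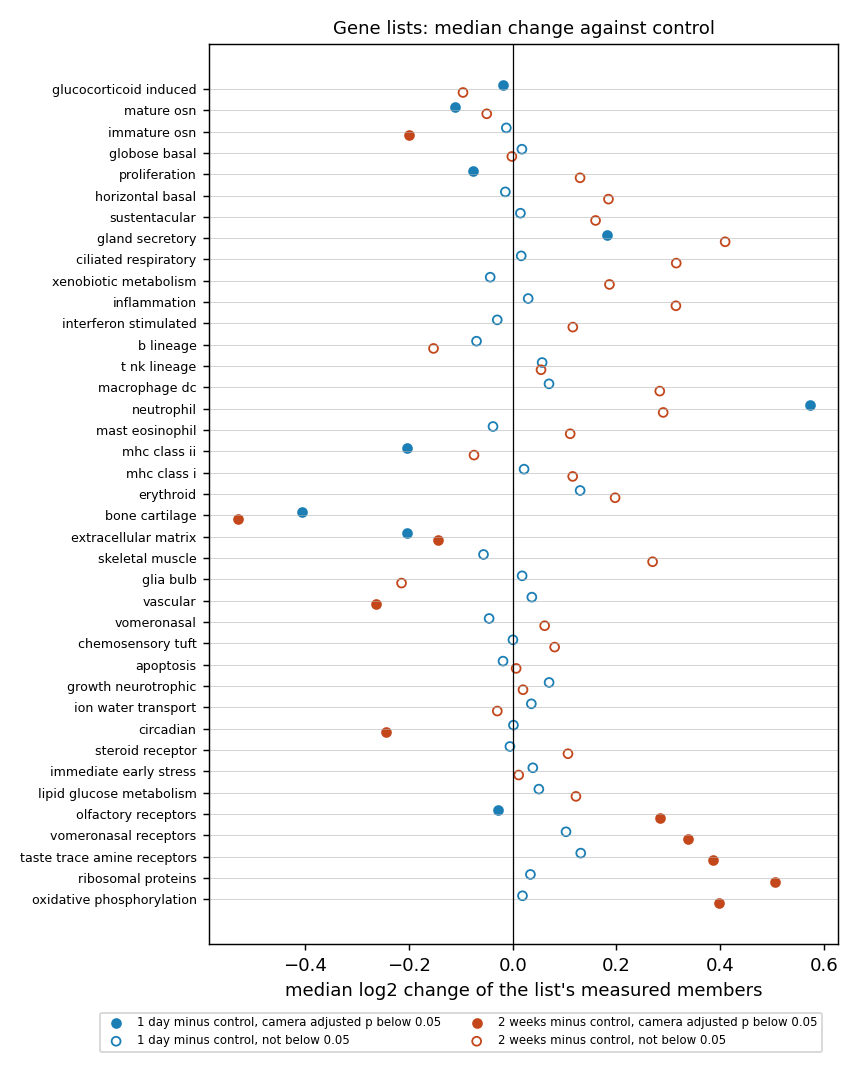
Median log2 change against control (horizontal axis) of the measured members of the 39 gene lists (vertical axis), 1 point for D1 and 1 for WK2, filled where the camera test with a preset correlation gave an adjusted p below 0.05. Bone and cartilage genes lay at -0.41 in D1 and -0.53 in WK2, ribosomal protein genes at 0.03 and 0.51. No filled point held with an estimated correlation.

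The comparison of WK2 with D1 asks where the long and the short treatment differed. Ccl20, Wdfy1 and clock genes were among those that differed. Dbp was 7.54-fold lower in WK2 than in D1 (log2 -2.92 ± 0.22 SE, adjusted p = 0.00274, limma), Ciart 3.23-fold lower (adjusted p = 0.0275), and Tef 3.21-fold and Per2 3.03-fold lower (both adjusted p = 0.0178). Arntl was 3.49-fold higher (adjusted p = 0.00955) and Ccl20 7.61-fold higher (adjusted p = 0.0323), at 1050 ± 632 in D1 and 8039 ± 3476 (SD, n = 3) in WK2. Muc15, a membrane mucin, was 3.74-fold higher (adjusted p = 0.00802), at 162 ± 8.53 in D1 and 745 ± 64.8 in WK2, and Cthrc1 3.72-fold higher (adjusted p = 0.0178).

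Btg4 (3.25-fold), Cgref1 (2.64-fold) and Eda2r (2.40-fold), a receptor of the tumour necrosis factor family, were also higher in WK2 than in D1, and Wdfy1 (4.70-fold), Cys1 (2.54-fold), Tspan4 (2.24-fold) and Apcdd1 (log2 -1.32) lower. The dimmer probe of Wdfy1 gave -0.62 here, beside -2.23 on the brighter one. Prss35 lay at 1.15 with an adjusted p of 0.0527 and did not pass. In all, 22 features passed the limma test, 7 higher and 15 lower in WK2, of which 16 were named genes. The fit of the D1 and WK2 arrays alone called 2 genes. Leaving out 1 array left 10, 27 or 6 genes (control replicates 1, 2 and 3), 1, 3 or 1 (D1 replicates 1, 2 and 3) and 6, 10 or 4 (WK2 replicates 1, 2 and 3).

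The median over all features was 0.10 in WK2 against D1, and the list medians given here are not relative to it. Of 17 circadian genes, 1 was higher and 4 lower in WK2 than in D1 over all genes, and 4 higher and 7 lower adjusted over the list alone. Inflammation genes had a median of 0.35, with Ccl20 past the test over all genes and 4 members higher adjusted over the list alone, the others being Cxcl1 (2.23), Ccl11 (1.06) and Il33 (0.58). Of 39 matrix genes 0 passed over all genes, while 9 were higher and 5 lower adjusted over the list alone. Vascular genes had a median of -0.22 and immature neuron genes of -0.20, with 0 past the test over all genes and 4 and 2 lower adjusted over the list alone. Ribosomal genes (median 0.45), oxidative phosphorylation genes (0.35), olfactory receptors (0.32) and taste and trace amine receptors (0.24) had 0 genes past the test over all genes or adjusted over the list alone.

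The preset camera test called the circadian (adjusted p = 0.00325), vascular (0.000775) and immature neuron (0.00423) lists lower in WK2 than in D1. It called the inflammation (0.0148), ribosomal (1.50e-05), oxidative phosphorylation (0.000127), olfactory receptor (1.60e-08) and taste and trace amine receptor (0.00798) lists higher. With an estimated correlation each of these 8 had adjusted p = 0.943. The inflammation call ended without D1 replicate 3 (0.215), and the taste and trace amine receptor call ended under cyclic loess (0.0634). Across the other scalings and the arrays left out, the other 6 calls held.

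No gene passed in both D1 and WK2 against control, where limma called 0 in D1. Of the 22 features that differed between WK2 and D1, 19 also passed in WK2 against control in the same direction, 13 of them named genes. Across features, which are not independent replicates, the D1 and WK2 changes had r = 0.54 and covariance 0.0587. With unchanged groups simulated against the same controls, the median r was 0.60 (95% of simulations from -0.28 to 0.90) and the median covariance 0.0345 (-0.00849 to 0.109), and 68.6% of features moved the same way, beside 68.8% observed. The observed values lay inside these simulated intervals, so no relation beyond the shared controls was shown, and the 3 control arrays could not be split into 2 sets of at least 2.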

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

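The tests of exchanged labels, of time of day, of the correlation between the 2-week change and the axis within groups, and of scaling and intensity by list were chosen after the results were seen, and so were leaving out 2 arrays together and the covariate for that axis. The 3 patterns below were picked from all results of these data, 117 list tests among them. Groups of 3 arrays were not tested for outlying samples.

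The direct test of the WK2 arrays against the D1 arrays gave differences between these groups, whose cause it does not show. It called 22 features. Among the named genes were Ccl20 (log2 2.93), Muc15 (1.90), Cthrc1 (1.90), Arntl (1.80), Btg4 (1.70), Cgref1 (1.40) and Eda2r (1.26) on the higher side in WK2. On the lower side were Dbp (-2.92), Wdfy1 (-2.23), Ciart (-1.69), Tef (-1.68), Per2 (-1.60), Cys1 (-1.35), Apcdd1 (-1.32) and Tspan4 (-1.16). Lists that differed by the preset camera test were immature neurons (median -0.20), vascular (-0.22), circadian (-0.34), inflammation (0.35), olfactory receptors (0.32), taste and trace amine receptors (0.24), ribosomal proteins (0.45) and oxidative phosphorylation (0.35). The median over all features was 0.10 in this comparison, and these list medians are not relative to it. None of these 8 list calls held, with adjusted p = 0.943 for each with an estimated correlation. The fit of the D1 and WK2 arrays alone called 2 genes.

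Other splits of the arrays are too few to give a share under 0.05. For D1 against control the real split gave 0 genes and 10 of the 10 splits gave as many, the highest of the others giving 2. For WK2 against control the real split gave 379 and was the 1 split with as many, the highest of the others giving 2. For WK2 against D1 the real split gave 22 and was the 1 split with as many, the highest of the others giving 3.

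Zbtb16 and Fkbp5, which glucocorticoids induce in many tissues, lay below control in WK2 (Zbtb16 at -2.44, and Fkbp5 at -1.29 without passing). Under 3 other scalings of the arrays the change nearest to 0 was -1.24. Array medians on the log2 scale spanned only 10.29 to 10.55, so these scalings could hardly have removed changes of this size. The small span, more than the test, argues against scaling. With 1 array left out the change nearest to 0 was -0.895, for Fkbp5 without WK2 replicate 3, just short of the bound set for excluding 1 array as the cause, so this stays open for Fkbp5, while Zbtb16 stayed at -2.20 or lower but lost its call in 7 of 9 such fits (adjusted p 0.0530 to 0.148). Exchanged control and WK2 labels cannot be told apart from a true difference. They would also put the chemokines Cxcl1 and Ccl20 on the side dexamethasone usually gives. Mt1 (0.66, past the test) and Dusp1 (0.59, not past it) lay above control as the labels give it. The limma call of Mt1 ended with any 1 array left out except WK2 replicate 1 (adjusted p 0.0686 to 0.148). In D1, Zbtb16, Fkbp5 and Tsc22d3 lay below control and Mt1, Sgk1 and Per1 above it, none past the test. The D1 values of Zbtb16, Fkbp5, Mt1, Sgk1, Cxcl1 and Ccl11 lay between control and WK2. Tsc22d3 and Ccl20 were lowest in D1 and Per1 was highest there. These mixed positions do not decide the question. The glucocorticoid-induced list, whose fall as a whole an exchange would give, was not called by camera (16 above and 22 below, adjusted p = 0.111, but 0.0148 without WK2 replicate 1). The bone and cartilage list, which dexamethasone would be thought to lower, lay below control with an unadjusted camera p of 0.0625 at an estimated correlation. A biological alternative, such as low corticosterone after repeated dosing with collection long after the last dose, may also apply and was not tested.

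Clock genes differed between WK2 and both other groups. A clock score, the mean of 3 activators (Arntl, Clock and Npas2) minus the mean of 9 output genes, was 1.70 higher in WK2 than in control (95% interval 1.22 to 2.18) and lay below control in D1 (-0.59, interval -1.07 to -0.11), and the WK2 difference kept 104% of its value with the axis within groups as a covariate (interval 74.8% to 133%, above the 50% set as the bound for that axis as the cause). It kept 103% under both quantile normalization and cyclic loess, which could change it only through shifts that depend on intensity. These values argue against such shifts, and the covariate against that axis, as the cause. Median centring (100%) cannot change a difference within an array, so it tested nothing here. The difference of 1.70, with activators higher and outputs lower, and the opposite one in D1 are what other times of day at collection would give, and shifts of the clock by dexamethasone would give them too; the labels hold no collection time that could separate them. A candidate explanation is thus a difference in clock phase, from either source.

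Ribosomal, oxidative phosphorylation and olfactory receptor genes stood above all features in WK2, by 0.37, 0.26 and 0.14. The correlation across genes between the WK2 change and the axis within groups was 0.191 in size, which argues against that axis as the whole cause, although WK2 replicate 3 dominates it and with the axis as a covariate the 3 shifts were smaller, at 0.30, 0.18 and 0.10. Under the less favourable of quantile and cyclic loess normalization the ribosomal list kept 110.5% of its median (95% bootstrap interval over members, which are not independent, 84.2% to 139.5%), which argues against scaling there, while oxidative phosphorylation kept 72.4% (63.9% to 98.5%) and the receptors 76.4% (57.1% to 91.2%), so part of theirs may come from scaling. Relative to features of the same intensity the ribosomal list kept 125% (106% to 160%), which argues against a dependence on intensity there. Oxidative phosphorylation kept 113.7% (93.2% to 134%), but its median member lay in bin 10, the brightest. A comparison within bins cannot remove a trend inside that bin, so a dependence on intensity stays open for this list. The receptors kept 54.7% (35.8% to 74.0%), so much of their shift may be that of dim features. Without control replicate 2 and WK2 replicate 3, 55.1% was left on average (0.24, 0.14 and 0.05 in the same order, the last under 50% of its value). The olfactory receptor call of the preset camera test also ended (adjusted p = 0.317). These arrays are the lowest control array and the highest WK2 array on principal component 1 (-53.0 and 63.3). Leaving out such extremes shrinks a difference along that component whatever its cause. Whether these arrays carry the shift therefore stays open, and so does a response to dexamethasone.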

How the results depend on the processing

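The smaller pseudocount, the 2 arrays left out together and the covariate were chosen after the data were seen. In the 379 WK2 calls the groups do not overlap, so most alternatives, among them leaving out arrays, could not change a sign and show nothing about it. Only the 3 scalings, the mean of probes and the covariate could. All 379 kept their sign under these, except 1 with the mean of probes (378 kept it). The number of genes called varied widely. Against 379 genes in WK2 versus control, quantile normalization gave 1260, median centring 1523, cyclic loess 607, leaving out the dimmest 25% of features 616 and the dimmest 50% 1167, array weights 2748, a pseudocount of 500 777 and an adjusted p under 0.1 3609. Lower counts came from the replicate block (1), the 2 groups alone (0), a minimum fold of 2 (185), a pseudocount of 16 (132) and both arrays left out (0), while the covariate gave 1525. Leaving out 1 array gave 1 to 966. Against 22 genes in WK2 versus D1 the counts were 76, 53 and 51 under the 3 scalings, 37 without the dimmest 25%, 134 with array weights, 13 with a pseudocount of 500, 69 at an adjusted p under 0.1, 8 with the replicate block, 2 for the 2 groups alone and 2 without both arrays, and 1 to 27 with 1 array left out. The cause was not tested, except that a looser threshold or a minimum fold sets its own count, and fewer arrays leave fewer degrees of freedom.

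In D1 versus control and in the overlap of D1 and WK2, every alternative gave 0 genes except 1 array left out, which gave 0 to 1. Of the 379 calls, 362 also passed under quantile normalization and 376 with median centring. The share of lower calls in WK2 versus control was 73.4%, and 85.2% with median centring, 53.2% with array weights and 52.3% with the covariate. In WK2 versus D1 it was 68.2%, 80.3% with quantile normalization, 79.2% with median centring, 53.6% with the covariate, 37.5% with the replicate block and 25% without WK2 replicate 3 (4 calls). Of 52 named gene calls, 6 to 40 passed with 1 array left out. That 0 of them reversed there was fixed in advance, as their groups do not overlap. Of 511 named gene results, 14, none past the test, changed sign under some alternative. Named gene results not called here passed 329 times over the alternatives, and lists not called here 60 times.

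Of 27 list calls 0 passed with an estimated correlation or with fry, and 12 passed without the dimmest 50%. Under the other alternatives 20 to 27 passed. Without D1 replicate 2 the neutrophil list in D1 turned to the lower side (median 0.0956). There the preset camera test called the macrophage and dendritic list, not called before, lower (-0.157). Further immune lists not called before were called lower in that fit. These were B lineage (median -0.30, adjusted p = 1.15e-05), interferon-stimulated (-0.19, 0.00024), T and NK lineage (-0.12, 0.000312) and inflammation genes (-0.08, 0.00155). MHC class I (-0.23, 0.0061) and mast and eosinophil genes (-0.15, 0.0272) were too. Without D1 replicate 3 the macrophage and dendritic list was called higher (0.19). The neutrophil median was highest without control replicate 2 (1.198). The cause was not tested.

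Replicate numbers did not pair the arrays: 2 of 9 same-numbered pairs had deviations that correlated above 0.1, and 2 arrays correlated best with their own number. With the replicate number as a block 1 gene passed in WK2 versus control. How far signals lay above background was not given, and the pseudocount limits the folds of dim genes.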

Other observations

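Muc19, a gland mucin, and Qrich2 stood out in the control arrays, and both were chosen after their values were seen. Muc19 averaged 3573 ± 2749 (SD, n = 3) in control, 535 ± 154 in D1 and 428 ± 81.8 in WK2. Qrich2 averaged 5996 ± 5170 in control, 102 ± 12.1 in D1 and 122 ± 20.6 in WK2. In each gene 1 control array was as low as the treated groups. Neither gene passed in D1 or WK2 against control with all 9 arrays.

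Several cell type lists were not called by camera in WK2 against control. The median over all features was 0.14 there, and the list medians given next are not relative to it. Relative to all features, the ciliated, muscle and macrophage lists stood at 0.18, 0.13 and 0.14. B lineage and immediate early genes stood at -0.29 and -0.13. Ciliated respiratory cell genes had a median of 0.32 with 23 of 29 above control and Ccdc39 at 0.62, though 6 of 23 alternatives called that list. Skeletal muscle genes had a median of 0.27 with Mb, myoglobin, at 0.98. Macrophage and dendritic cell genes had a median of 0.28 with Adgre1 at 0.58, and B lineage genes a median of -0.15 with Spib at -1.38, called lower without control replicate 3 (adjusted p = 0.0236). Immediate early genes had a median of 0.01, with Fos at 1.04 and Nr4a1 at 1.05, 0 past the test over all genes, and 4 higher and 1 lower adjusted over the list alone. None of the members named here passed the limma test over all genes.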
